A study of Mus musculus with 4 samples.

How the data were processed

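Chromosome conformation was measured by 5C (chromosome conformation capture carbon copy, in which a pool of primers reads out ligation products between many restriction fragments of 1 region) in mouse embryonic stem cells (ESC) and in motor neurons (MN) differentiated from them. Each cell state was profiled in a wild-type (WT) line and in a line labelled Δ5|6:7|9, called the deletion line here. The study is known to concern CTCF sites of the HoxA cluster, and the label names the sites between Hoxa5 and Hoxa6 and between Hoxa7 and Hoxa9. CTCF is a DNA-binding protein found at boundaries between chromosome domains. Per the labels' protocols, ESC were kept with Lif, 1 µM of a MEK inhibitor and 3 µM of a GSK3 inhibitor. Embryoid bodies were patterned on day 2 with 1 µM retinoic acid and 0.5 µM smoothened agonist. Cells were fixed in 1% formaldehyde and cut with HindIII, and 5C primers were annealed to 3C libraries of 2 biological replicates per sample, per the labels' protocols.

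The deposited values are 1 insulation score per HindIII fragment and library, which the authors combined with a script named in the file headers. Bowtie 1 and the mouse build mm9 are named in the submitters' processing notes. The primer filter, the normalization of contacts, the window of the score and the way replicates were combined are not given in the sources used here. In each library the scores above 0 averaged 1.00, so the authors' values appear scaled to a common mean, and a score is a level relative to the library's own region. The direction of the score is not stated either. By the usual convention, a low score marks a fragment that few contacts cross, and a local minimum marks a boundary. A score at a fragment summarises contacts of its neighbours, so adjacent scores are not independent. The correlation of adjacent log2 ratios ran from 0.76 to 0.92 over the 4 comparisons.

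All 4 libraries listed the same 479 fragments from 50194861 to 53993599, with a median length of 5716 bp. The 9 fragments at each end were listed at 0 in all libraries and were left out, which left 461 scored fragments. Gaps between listed fragments took up 11.0% of the span. Read and contact counts were not used here, so the depth behind a score is unknown and no counting interval can be given. Each group had 1 library, so no comparison within a state or line has a replicate check. An additive fit of state and line to the log2 scores of the 4 libraries leaves 1 residual degree of freedom per fragment. It was run with limma over the 461 fragments, with moderated variances (3.4 prior degrees of freedom) and Benjamini-Hochberg adjustment. Its residual is the state-by-line difference, so it treats any such difference as noise.

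The tables also differ in their decimals, as an extra last digit of 5 was seen in 47.1% of WT ESC scores, 48.4% of deletion-line ESC scores, 53.6% of WT MN scores and none of deletion-line MN. Whether the deletion-line MN table rests on 2 replicates is thus uncertain, which bears on every value from that library.

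Log2 ratios of scores were computed per fragment for 4 comparisons: deletion line over WT in each cell state, and MN over ESC in each line. No pseudocount was needed. The files name no chromosome, and no mm9 annotation was used here, so single fragments were not assigned to genes. The HoxA cluster is generally known to lie on chromosome 6 at about 52.1 to 52.2 Mb in mm9. The grid bin of 100 kb from 52.1 to 52.2 Mb (19 fragments by midpoint, 52102714 to 52203348) was therefore summarised as the HoxA bin. Gene order, without coordinates, was taken from a RefSeq table of GRCm38.p6. The spread was taken from the rest of the region, the 395 scored fragments below 51.9 Mb or above 52.4 Mb. A value of the bin was set against every run of 19 consecutive fragments in the rest (359 runs), as a description of these libraries. Local minima of the log2 score were called at a prominence of 0.25. The procedure was checked on simulated data. A triangular log2 change of 0.5, or of 1, placed at random in noise like that of the deletion comparisons was located within 9 fragments in 100 of 100 draws, for each state and size.

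Before the data were examined, the plan had assumed contact counts. Shares of contacts between Hox domains, viewpoints of single Hox genes, the decay with distance and counting intervals could not be computed from scores. The planned insulation profile took their place, as the plan provided, with the deposited score replacing a score computed with a window of 50 kb. The rule for named items, written for contact pairs, was applied to fragments: the 5 largest increases and the 5 largest decreases of each comparison, and those at least 2-fold changed the same way in both states. A second list keeps, within each comparison and direction, sites at least 100 kb apart. That list, the additive fit, the HoxA bin, the rest, the call of local minima and all alternatives (other summaries of the bin, scalings, bin edges and prominences) were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.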

Results

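Insulation scores were obtained for 461 HindIII fragments, within a listed span of 3.80 Mb around the HoxA cluster, in 4 libraries: WT ESC, deletion-line ESC, WT MN and deletion-line MN, with 1 library each. HoxA holds 11 Hox genes, which encode transcription factors that specify position along the body axis. With rising coordinate the order is Skap2, the HoxA cluster, Evx1 and Hibadh, so the low-coordinate side of the cluster faces Skap2 and the high-coordinate side, with Hoxa13, faces Evx1. The scores ranged from 0.401 to 2.00 in WT ESC (SD 0.249 over fragments), from 0.375 to 1.92 in deletion-line ESC (SD 0.249), from 0.323 to 1.87 in WT MN (SD 0.275) and from 0.299 to 1.95 in deletion-line MN (SD 0.277). Outside the cluster the profiles of both lines were close. Across the 395 fragments of the rest of the region, the Pearson correlation of log2 scores between lines was 0.97 in ESC and 0.99 in MN. These are correlations across fragments, which are not independent replicates.

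**Figure D1:**
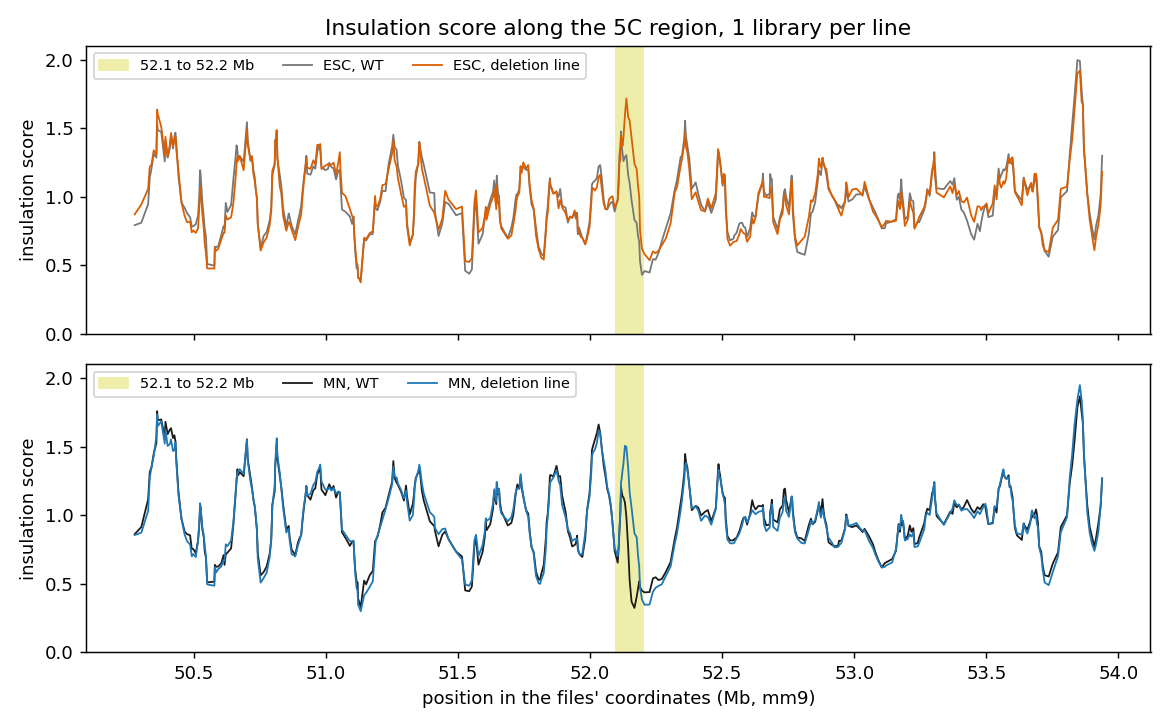
Insulation score (vertical axis, no unit, mean about 1 per library) against position in Mb for the 461 scored fragments, with ESC above and MN below. Each line is 1 library and the shaded band is the HoxA bin. In MN the WT and deletion-line profiles separate mainly in and beside the shaded band, where the WT MN score reached 0.323. In ESC they also separate elsewhere, as at 53473941 to 53477716 (log2 ratio 0.31) and 52802587 to 52822761 (0.30).

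The first comparison asked how loss of the 2 CTCF sites altered the structure of HoxA in stem cells. In ESC, scores within the HoxA bin were higher in the deletion line than in WT. The bin's mean score was 1.06 in WT and 1.26 in the deletion line, a mean log2 ratio of 0.29 (SD 0.27 over 19 fragments). Of these fragments 14 were higher and 5 were lower. None of the 359 runs of 19 fragments in the rest of the region had so large a mean, the highest being 0.10. This depends on the bin's edges: moved 50 kb lower, the bin averaged 0.096, inside the range of those runs. The 5 largest increases of all 461 fragments lay in the bin, between 52151568 and 52188538. The largest was at the fragment from 52179068 to 52183981, whose score was 0.716 in WT and 1.08 in the deletion line, 1.51-fold higher. The 11 fragments from 52134173 to 52209630, a stretch of 75.5 kb, each exceeded the highest log2 ratio of the rest (0.31). In WT ESC the minimum of the cluster lay at its Hoxa13 side, at 52190054 to 52203348, with a score of 0.430, the third lowest of the region. That fragment scored 0.619 in the deletion line, where the local minimum lay at 52217060 to 52233685 with a score of 0.537. The 5 largest decreases in ESC all lay outside the HoxA bin and its flanks, at 50543481 to 50549225 (log2 ratio -0.27), 50644526 to 50655903 (-0.24), 50539321 to 50543480 (-0.22), 51408882 to 51412357 (-0.22) and 50655904 to 50660690 (-0.18). In the list of separate sites, the increases after the first also lay outside the bin and its flanks. They were at 53473941 to 53477716 (log2 ratio 0.31), 52802587 to 52822761 (0.30), 51537493 to 51547731 (0.26) and 50280337 to 50322799 (0.22). With 1 library per line, these differences have no replicate check.

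The same question was put to motor neurons. In MN, the deletion line differed from WT most in the middle of the HoxA bin. The fragment from 52151568 to 52163061 scored 0.368 in WT and 1.05 in the deletion line, 2.86-fold higher, or a log2 ratio of 1.51. Its neighbour from 52163062 to 52173421, the lowest fragment of the whole WT MN profile, scored 0.323 in WT and 0.867 in the deletion line, 2.68-fold higher. The other members of the top 5 were 52148204 to 52151567 (2.21-fold), 52174043 to 52179067 (2.08-fold) and 52140924 to 52148203 (1.78-fold). In the rest of the region the highest log2 ratio was 0.16 and the SD was 0.059. Over the bin, the mean score was 0.754 in WT and 1.00 in the deletion line, a mean log2 ratio of 0.45 (SD 0.52 over 19 fragments). Of the 19 fragments 17 were higher, and the highest run of as many fragments in the rest had a mean of 0.073. With the bin moved 50 kb lower the mean was 0.21, still above every run. The median over the bin was lower, 0.27. Of the 19 fragments 11 exceeded every fragment of the rest.

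On the Hoxa13 side of the bin, MN scores were lower in the deletion line. The fragment from 52217060 to 52233685 scored 0.439 in WT and 0.348 in the deletion line, and that from 52203349 to 52209630 scored 0.437 and 0.346. These were 1.26-fold lower in both cases, with log2 ratios of -0.34 and -0.33, next to a lowest log2 ratio of -0.33 in the rest. The other decreases named by the rule were 52233686 to 52242792 (log2 ratio -0.29) and, far from the cluster, 51140456 to 51149556 (-0.33) and 51162857 to 51170185 (-0.24). At the prominence used, the local minima within the bin and up to 52242792 were 52102714 to 52107157 in both MN libraries, 52163062 to 52173421 in WT MN and 52203349 to 52209630 in deletion-line MN. WT MN also dipped at this last fragment, with a prominence of 0.24, just under the limit of 0.25, so a dip on the Hoxa13 side was seen in both lines. The HoxA bin and its flanks of 200 kb held 14.3% of the scored fragments. They held 86.1% of the summed squared log2 ratios of the deletion comparison in MN and 52.2% of those in ESC.

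**Figure D2:**
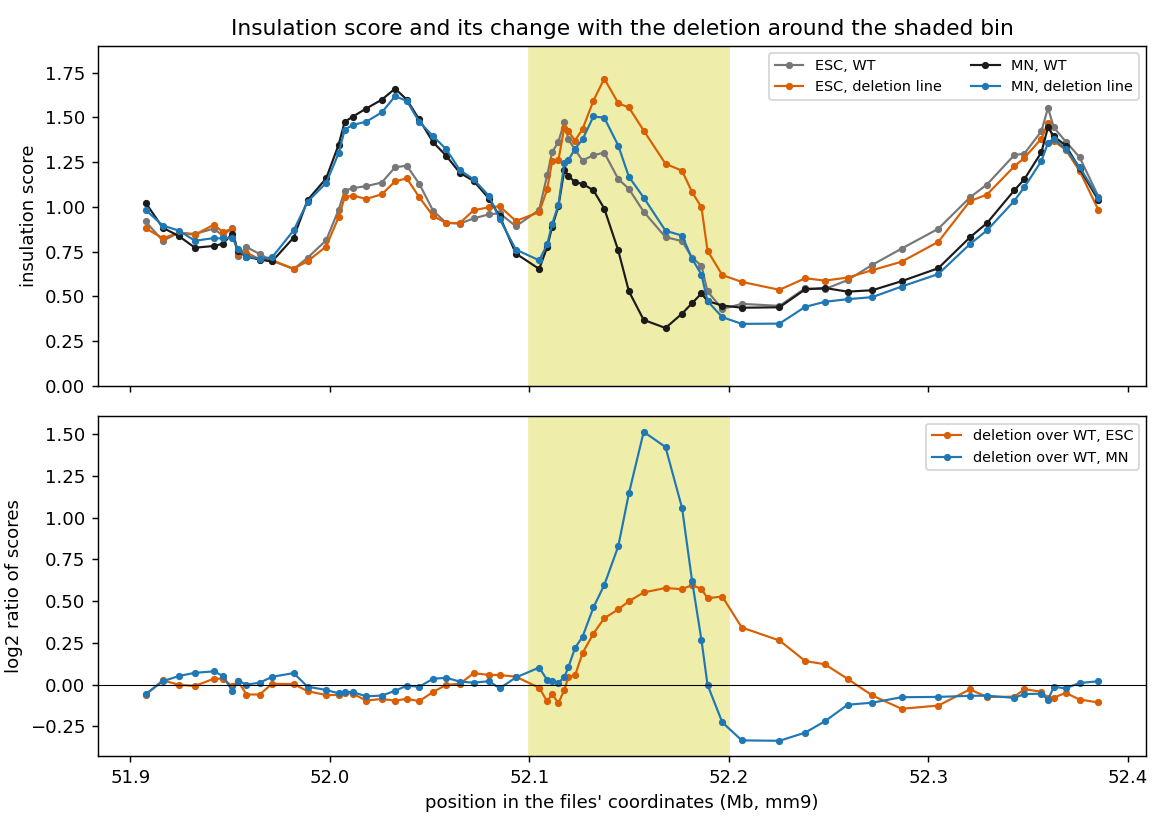
Insulation score of each library (upper panel) and log2 ratio of deletion line over WT (lower panel) against position in Mb from 51.9 to 52.4 Mb. Each point is 1 fragment in 1 library, without replicates, and the HoxA bin is shaded. In MN the log2 ratio reaches 1.51 inside the bin and is as low as -0.34 beyond it, and in ESC it is above 0 from 52118128 to 52265585, with a maximum of 0.60.

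The deletion's change in the 2 cell states was then set side by side. It was larger in MN than in ESC in the middle of the bin and had the opposite sign at its Hoxa13 end. At 52151568 to 52163061 the log2 ratio was 0.55 in ESC and 1.51 in MN, a difference of 0.96. At 52190054 to 52203348 it was 0.53 in ESC and -0.23 in MN, a difference of -0.75. The difference in the rest ranged from -0.36 to 0.32. Over 9 fragments from 52130049 to 52188538, scores were higher with the deletion by at least 0.2 on the log2 scale in both states, with mean log2 ratios of 0.50 in ESC and 0.88 in MN. Over 3 fragments from 52190054 to 52233685 they were at least that much higher in ESC and lower in MN. No fragment of the rest met either criterion. No fragment was changed at least 2-fold the same way in both states. The 4 fragments that were at least 2-fold higher were so in MN, and none was in ESC. The difference of the bin means, MN minus ESC, was 0.16, but it was -0.13 when medians were taken, so the bin as a whole does not order the states. With 1 library each, a test of the difference between states has no residual degree of freedom. Fitting state and line additively over the 4 libraries (limma) asks instead for a deletion change common to both states. At an adjusted p below 0.05 it gave 1 fragment of 461, 52179068 to 52183981 in the bin, with a mean log2 ratio of 0.61 (adjusted p 0.018). Fragments whose change differs between the states, as at the peak in MN, cannot pass this fit easily, since that difference is its residual. The fragment that passed lies where the 2 changes cross, at 0.60 in ESC and 0.62 in MN, so its residual is small. Beside it, the changes in ESC and MN were 0.57 and 1.06 at 52174043 to 52179067, and 0.57 and 0.27 at 52183982 to 52188538. The adjusted p thus does not measure a spread between replicates.

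Differentiation of WT cells was compared next. From ESC to MN, WT scores were lower through the HoxA bin and higher beside it on the Skap2 side. The bin's mean score was 1.06 in ESC and 0.754 in MN, with a mean log2 ratio of -0.54 (SD 0.41). Of 19 fragments 18 were lower, and the lowest run of as many fragments in the rest had a mean of -0.22. With the bin moved 50 kb lower the mean was -0.21, inside the range of the runs. The largest decrease of all was at 52151568 to 52163061, from 0.973 to 0.368, 2.64-fold lower. It was followed by 52163062 to 52173421 (2.57-fold), 52148204 to 52151567 (2.08-fold), 52174043 to 52179067 (2.01-fold) and 52179068 to 52183981 (1.55-fold). This comparison and the deletion comparison in MN use the same WT MN library, so a deviation of that library alone would enter both. The bin's Hoxa13-side minimum in WT ESC, at 52190054 to 52203348, scored 0.430 in ESC and 0.449 in MN. The largest increases lay elsewhere, at 51309849 to 51325297 (log2 ratio 0.60), 51325298 to 51333544 (0.58), 53449496 to 53458518 (0.57), 51984842 to 51992856 (0.54) and 53435602 to 53449495 (0.52).

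In the deletion line, MN scores were lower than ESC scores at all 19 fragments of the HoxA bin, with a mean log2 ratio of -0.38 (SD 0.21). The lowest run in the rest was -0.28, and the bin moved 50 kb lower averaged -0.090, inside the range of the runs. The bin's mean score was 1.26 in ESC and 1.00 in MN. At 52151568 to 52163061 the log2 ratio was -0.44, against -1.40 in WT. At 52203349 to 52209630, on the Hoxa13 side, it was -0.75, with scores of 0.581 in ESC and 0.346 in MN, against -0.070 in WT. The named decreases were this fragment, its neighbours 52190054 to 52203348 (-0.69), 52183982 to 52188538 (-0.68) and 52188539 to 52190053 (-0.67), and, first of all, 51140456 to 51149556 (-0.75). That last fragment lies about 1 Mb below the cluster and had a log2 ratio of -0.40 in WT. Over the rest of the region, the SD of single-fragment log2 ratios was 0.19 for differentiation in WT and 0.20 in the deletion line, against 0.088 for the deletion in ESC and 0.059 in MN. In the additive fit (limma), 100 fragments were higher and 106 lower in MN than in ESC at an adjusted p below 0.05, 14 of them in the HoxA bin. Each state has 1 library per line there, and adjacent fragments are dependent.

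Beside the cluster on the Skap2 side, scores were higher in MN than in ESC in both lines. Over 14 consecutive fragments from 51979635 to 52068772 (89.1 kb), each at least 0.25 higher in log2 in both lines, the mean log2 ratio was 0.45 (SD 0.055) in WT and 0.49 (SD 0.051) in the deletion line. The mean score went from 0.999 to 1.36 in WT and from 0.959 to 1.35 in the deletion line. In the deletion line, 4 of the 5 largest increases with differentiation lay in this stretch, at 51984842 to 51992856 (log2 ratio 0.56), 52048523 to 52055037 (0.56), 51992857 to 52003398 (0.54) and 52055038 to 52061484 (0.54), and the fifth, the largest, at 51309849 to 51325297 (0.58). The highest run of 14 fragments in the rest had a mean of 0.30 in WT and 0.33 in the deletion line. The stretch was picked from the same scores by the limit of 0.25, so this does not exclude noise. At the first fragment of the HoxA bin, 52102714 to 52107157, scores were lower in MN in both lines, from 0.984 to 0.653 in WT and from 0.971 to 0.701 in the deletion line. This fragment was a local minimum in both MN libraries and in neither ESC library. The nearest minimum of WT ESC was the fragment before it, 52087189 to 52099306, with a score of 0.892.

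**Figure D3:**
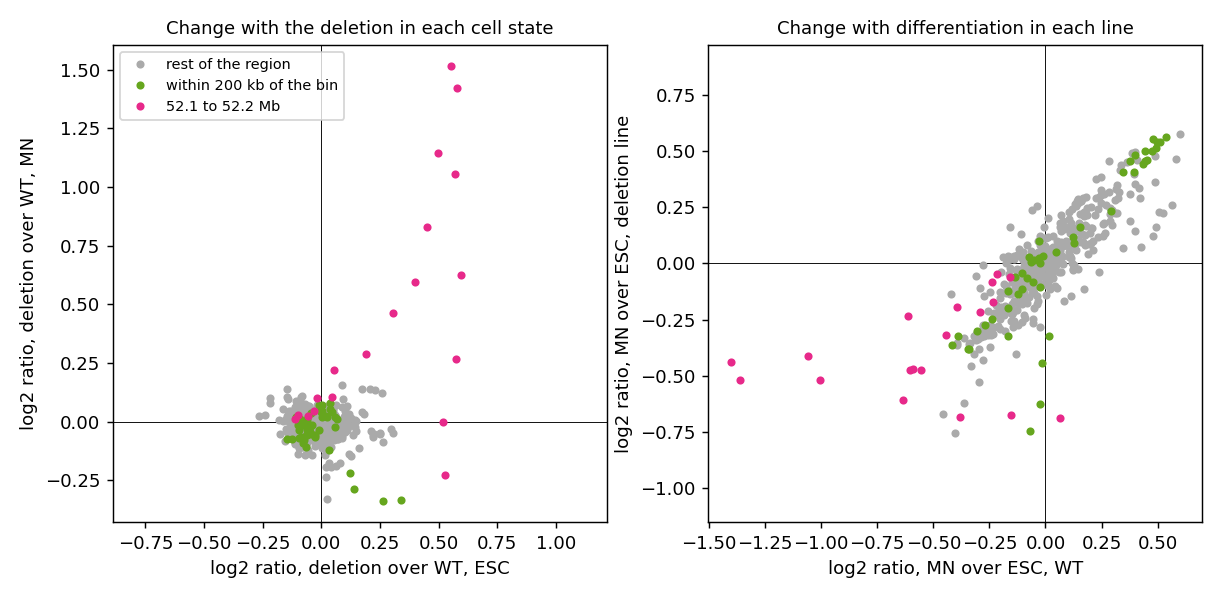
Log2 ratio of the insulation score per fragment: left, deletion line over WT in ESC (horizontal) and MN (vertical); right, MN over ESC in WT (horizontal) and the deletion line (vertical). Points are the 461 fragments, coloured by position. Deletion changes of the rest form a round cloud around 0 (Pearson r -0.053), whereas differentiation changes of the rest lie along the diagonal (r 0.85).

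Across the region, 24 local minima were called in WT ESC, 26 in deletion-line ESC, 24 in WT MN and 25 in deletion-line MN. Of the WT ESC minima 20 lay within 20 kb of a minimum of deletion-line ESC, and 21 of the WT MN minima lay within that distance of one in deletion-line MN. Between states, 18 of the 24 WT ESC minima lay that close to a minimum of WT MN, and 21 to one of deletion-line MN. Of the 26 deletion-line ESC minima, 16 lay that close to a minimum of WT MN and 19 to one of deletion-line MN. The fragment from 51123835 to 51140455 was the lowest of the profile in WT ESC (0.401), deletion-line ESC (0.375) and deletion-line MN (0.299), and the second lowest in WT MN (0.329).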

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

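The tests in this part were chosen after the results were seen. One result stood out because its direction differed between the cell states: over 3 fragments from 52190054 to 52233685, at the Hoxa13 side, the deletion line was higher than WT in ESC (mean log2 ratio 0.38) and lower in MN (mean -0.30). The difference, MN minus ESC, was -0.68, and it was not tested, since each state has 1 library per line. The mean scores there were 0.445 in WT ESC, 0.579 in deletion-line ESC, 0.441 in WT MN and 0.359 in deletion-line MN. A smaller difference with the same signs was seen at another local minimum, 53727321 to 53745028, with log2 ratios of 0.081 in ESC and -0.18 in MN. The minimum at 51537493 to 51547731 was instead higher in both states (0.26 and 0.12).

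The lowest of 391 runs of 3 fragments in the rest reached only -0.32. The stretch was picked from the same data for its opposite changes, so this does not exclude noise. Deletion-line MN was also lower than WT MN at other low-scoring sites, such as 51140456 to 51149556 (0.416 against 0.523) and 50745600 to 50760990 (0.508 against 0.561). It was higher at others, such as 51517414 to 51537492 (0.496 against 0.451). The MN deletion table differs from the others in its decimals: none of its 461 scores carries an extra last digit of 5 after 9 decimals, as a mean of 2 such values often would, against 47.1% in WT ESC, 48.4% in deletion-line ESC and 53.6% in WT MN. It may therefore rest on 1 replicate, or have been rounded differently, and this doubt bears on every value of deletion-line MN. The SD of deletion over WT in the rest was 0.059 in MN and 0.088 in ESC. Each SD belongs to a ratio of 2 libraries, so it cannot show how noisy the deletion-line MN table is by itself. A deviation of 1 library at this stretch stays open, as does a response to the deletion that depends on the cell state, which is untested.

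A second pattern is the higher scores with the deletion inside the HoxA bin. The rest of the region had a median log2 ratio of -0.016 in MN and -0.015 in ESC, so no upward shift of the whole profile was left. The scores appear scaled to a common mean, which by itself keeps this median near 0. It therefore cannot decide whether the authors' scaling plays a part. The ESC comparison does not use the WT MN library, so a deviation of that library cannot explain the increase in ESC. There the bin mean was 0.29 against a highest run of 0.10, though the bin moved 50 kb lower gave 0.096, inside the runs. The increase in MN does use the WT MN library, and the ESC values cannot exclude that library as its source. The excess of MN over ESC at 52151568 to 52163061, 0.96 on the log2 scale, cannot be told apart from a deviation of that library, because only 1 WT MN library was analysed here. An effect of the deletion, as the design names it, remains a hypothesis without replicates.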

How the results depend on the processing

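Each bin mean was recomputed under 8 alternatives, all chosen after seeing the data. Of the 40 values, 24 moved by less than the SD of runs of 19 fragments in the rest, 14 moved by more with the same sign, and 2 reversed. The bin moved 50 kb higher held 11 fragments but was judged by the same SD. The causes were not tested. For the deletion in ESC (0.29), the median gave 0.40, weighting by length 0.38, and moving the bin by 50 kb 0.096 (lower) or 0.44 (higher). For the deletion in MN (0.45), the median gave 0.27, leaving out the fragment of the largest change 0.39, the ratio of mean scores 0.41, weighting by length 0.58, quantile normalization 0.41, and the moved bins 0.21 and 0.32. For differentiation, the lower bin gave -0.21 in WT (-0.54) and -0.090 in the deletion line (-0.38), where the higher bin gave -0.57. The excess of MN over ESC (0.16) reversed with the median (-0.13) and the higher bin (-0.12). Of 16 alternatives for single fragments and counts of minima, 13 stayed close (within the SD of the rest for fragments, within 1.5-fold for counts). The exceptions were the largest change in MN, 1.38 after quantile normalization, and the minima at a prominence of 0.5, which were 15 in each MN library. At that prominence WT ESC had 21 minima and deletion-line ESC had 20. The alternatives fixed beforehand for contact pairs (denominator, distance, primer balancing, count filters, windows of 25 and 100 kb) were not run, since scores do not allow them. With the lower bin, only the deletion in MN stayed beyond every run of the rest. No replicate could be left out, since each group has 1 library. Pairing the lines within states, by the additive fit, gave a bin mean of 0.37 for the deletion and 1 fragment at an adjusted p below 0.05 (limma). This bin mean is the average of the ESC and MN values by construction, so it is not a further check. The depth behind the scores is unknown, so what it limits cannot be said.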

Other observations

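The test of differentiation below was set before its value was seen; the others in this part were chosen afterwards. Outside the cluster, the changes from ESC to MN recurred in both lines, which share no library. Across the 395 fragments of the rest, the log2 ratios of WT and the deletion line correlated at a Pearson r of 0.85 (Spearman 0.84), and 322 fragments (81.5%) had the same sign. None of 376 circular shifts of one profile against the other gave so high a value, the highest being 0.20. All 18 sites named as largest in either line, 13 of them in the rest, had the same direction in both lines, though they were picked for their size in one. The gap of 100 kb held only within each line and direction. Some of these sites are thus close or adjacent, such as 51140456 to 51149556 and 51149557 to 51155165, and do not count as independent. Of the 13, 9 kept at least 50% of the larger line's change in the other line: for example, 51309849 to 51325297 was higher in MN by 0.60 (WT) and 0.58 (deletion line), 51685848 to 51691892 by 0.41 and 0.46, and 52588662 to 52600674 by 0.40 and 0.50. Lower in MN were 51149557 to 51155165 (-0.46 and -0.67), 51513436 to 51517413 (-0.33 and -0.46) and 52896960 to 52908680 (-0.40 and -0.35). The other 4 fell below 50%: 53449496 to 53458518 (0.57 in WT and 0.26 in the deletion line), 52797263 to 52802586 (0.51 and 0.23), 50617031 to 50625578 (-0.42 and -0.13) and, larger in the deletion line, 53745029 to 53758621 (-0.13 and -0.40). A shrinkage of sites picked as largest is expected by chance too, and was not tested. The sites of similar size in both lines may mark structural changes of differentiation that do not require the deleted CTCF sites. A difference between the ESC and MN libraries in preparation would also be shared by the lines and was not tested.

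Taken over the whole rest, the deletion's changes did not correlate between cell states. Their correlation across the same fragments was -0.053, inside the range of the shifts (-0.23 to 0.23), and 49.6% of fragments had the same sign. A weak correlation within that range is not excluded. One stretch was higher in both states: 3 adjacent fragments from 51517414 to 51557857 lay more than 2 SD above 0 in each, with log2 ratios of 0.21, 0.26 and 0.23 in ESC and 0.14, 0.12 and 0.13 in MN. As many as 3 occurred in 7 of the 376 shifts (1.9%). A lasting difference between the lines at this stretch is a candidate, with no replicate to check it.

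At the fragment where WT MN was lowest, 52163062 to 52173421, deletion-line MN was higher than WT ESC by only 0.061 on the log2 scale, whereas WT MN was lower than WT ESC by a log2 ratio of -1.36. This comparison crosses line and state. Within the deletion line the fragment was lower in MN than in ESC, by a log2 ratio of -0.52 (0.867 against 1.24), and WT ESC scored 0.831. Over the HoxA bin, deletion-line MN over WT ESC averaged -0.092 (SD 0.26), and the log2 profiles of these libraries correlated at 0.89 across the bin's fragments. Deletion-line MN correlated more closely with deletion-line ESC (0.97).

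Scores spread more widely in MN than in ESC. The SD of log2 scores over the rest was 0.39 in WT MN and 0.41 in deletion-line MN, against 0.36 in both ESC libraries. The SD of second differences along the rest was 0.17 and 0.15 in MN but 0.21 in both ESC libraries, so differences between close neighbours were not larger in MN. Adjacent scores are not independent, and noise shared by neighbours would be missed by this measure, so noise is not excluded. At a prominence of 0.5, 15 minima were called in each MN library, against 21 in WT ESC and 20 in deletion-line ESC. The wider spread thus did not come with more strong minima, and sharper domains in MN are not shown. A difference in depth or in the authors' processing stays open.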
